A study of Sinorhizobium meliloti with 6 samples.

How the data were processed

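RNA from Sinorhizobium meliloti, a soil bacterium that fixes nitrogen inside legume root nodules, was measured by RNA sequencing in 6 libraries. There was 1 library for each combination of 2 strains and 3 cell-cycle phases. The strains were Sm1021, labelled wild type, and ntrX18, whose label names a knock-down mutation of ntrX, the response regulator of the NtrY-NtrX sensor pair. The phases were G1, S and G2. Per the labels, cultures were synchronised by 270 min without a carbon source. The labels do not name separate cultures, so p-values measure only the spread between these 6 libraries. The extraction text in the labels speaks of retinas, which a bacterium lacks, so only the Trizol reagent and the TruSeq RNA kit that it names are taken from it.

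The deposited table gives counts and FPKM values for 6292 genes in each library, with coordinates on the chromosome and on the megaplasmids pSymA and pSymB. Bowtie2, TopHat and HTSeq are named in the submitters' processing notes. Their versions, the genome build and the strand setting are not given in the sources used here. The deposited count columns are whole numbers, and total 13490996 to 16460872 per library. The deposited FPKM columns equal the count divided by gene length and column total for 100% of 37120 nonzero values, within a tolerance of 0.1%, so only the counts were tested. Of the genes, 1799 had a symbol, 2250 were named only by a locus tag and 2243 by neither. The last are written as gene with the number the deposited table gives. The reference gene table at hand belonged to the assembly of another strain and was not used. The counts held 0 rRNA or tRNA genes. Reads of overlapping genes such as ntrY and ntrX, of genes on opposite strands, and of near-identical copies such as the fixK and fixN genes cannot be told apart with certainty, so the values of such genes are uncertain.

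Counts were scaled with edgeR's TMM factors, which ranged from 0.680 in the ntrX18 G1 library to 1.16 in the ntrX18 G2 library. Values are given as CPM, counts relative to the library total after this scaling. The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16, limma 3.58.1, R 4.3.3), with strain and phase as terms, after edgeR's low-count filter, which kept 6128 genes and removed 164. Benjamini-Hochberg adjusted p-values under 0.05 were called. With 1 library per strain and phase this fit has 2 residual degrees of freedom, and its error is the part of the strain difference that varies between phases, with a common biological coefficient of variation of 36.0%. It therefore tests the strain difference shared by the phases and the phase change shared by the strains, and does not test whether a phase change differs between strains. In comparisons of 1 library with 1 there was no replicate check and no test. For these, log2 ratios were taken with a prior count of 2, and genes were counted past a size rule, a log2 ratio of at least 1 in either direction with a mean CPM of at least 10.

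Gene lists, 37 in all, were matched to the deposited table by symbol. They were tested with camera at a preset correlation of 0.01 between genes, again with an estimated correlation, and with fry, and were adjusted over the 37 lists. In comparisons of 1 library with 1, a list's median was placed among 10000 random lists of the same size, matched on deciles of expression. Genes of the random lists were drawn independently, so these places describe a list and are no test where its genes vary together. Intervals of ratios are exact binomial at 95%, and the lowest level read as detected is 3 counts. Intervals and this floor cover counting error only. Replicon shares were compared with a two-sided exact permutation test. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were also used.

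The groups, the tests, the gene lists and the rule for naming genes were chosen before the data were examined. The rule named a fixed set of regulators and cell-cycle genes in every library, the 12 largest rises and falls of the strain effect, and the 6 largest of each phase effect, past the threshold and with 1 direction in every phase or strain. Where none passed, it named the 5 genes with the smallest p. It also named the 4 largest values each way in each untested comparison and up to 4 members with the smallest p of each list discussed. The largest-change parts of the rule asked for a mean CPM of at least 10 and left out 143 transposase genes. Genes named outside this rule are pointed out as chosen after their values were seen. The regulators gcrA, sciP, visN and rem had no matching symbol and were not analysed here.

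Alternatives were edgeR's RLE factors, library size alone, other low-count filters, DESeq2 (version 1.42.0), limma-voom, fits with strain alone or phase alone, other prior counts and size rules, and each library left out. A fit without both G1 libraries was added after the results were seen. The code was tested on simulated data with 6128 genes, 50 of them changed at each fold. For the strain effect, 14% were recovered at a fold of 2, 90% at 4 and 100% at 16 and at 64. For S against G1 the shares at folds of 2 and 4 were 2% and 50%, for G2 against G1 2% and 72%, and for G2 against S 6% and 44%. With no change simulated there were 0 calls in each of these comparisons. With changed genes present, the unchanged genes called were 5 for the strain effect, 0 for S against G1, 2 for G2 against S and 5 for G2 against G1. Counts of each gene were simulated independently, with no strain difference that varied between phases. In the data that variation is the error of the fit, so these shares and calls check the code and give no rates for the data. The size rule found 200 of 200 genes changed 4-fold, with 0 false calls, in libraries simulated with counting error only. Variation between cultures was not simulated, so these 0 false calls give no rate for the size rule in the data.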

Results

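The ntrX18 strain was compared with Sm1021 in G1, S and G2, with 1 library for each strain and phase. The title of the series asks which genes are transcribed differently, and cyclically, in both strains. Library totals were 15110996, 15666436 and 16460872 counts in Sm1021 and 13490996, 15529633 and 15570686 in ntrX18, in the order G1, S, G2 that is used throughout. The median gene had 605, 537 and 598 counts in Sm1021 and 302, 581 and 618 in ntrX18. The 10 most abundant genes took 19.3% of the counts in Sm1021 G1 and 20.9% in ntrX18 G1, against 9.49% to 13.3% in the other libraries. Scaling by library size alone moved the median of all genes by -0.55 log2 in the ntrX18 G1 library and by 0.052 to 0.21 in the others, so ratios that use ntrX18 G1 are relative to that shift. Across genes, S and G2 were nearly alike within each strain, with a Pearson r of log2 values of 0.992 in Sm1021 and 0.987 in ntrX18. G1 and S were less alike, with r of 0.83 in Sm1021 and 0.882 in ntrX18, and the G1 libraries of the strains were at 0.785. Genes are not independent replicates, so these r describe the libraries.

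The ntrX transcript was only slightly lower in ntrX18 than in Sm1021. The gene (chromosome 1573356 to 1574720) stood at 169.8, 204 and 175 CPM in Sm1021 and at 151, 162 and 135 CPM in ntrX18. The ratios were 0.887 (0.830 to 0.947) in G1, 0.795 (0.755 to 0.837) in S and 0.773 (0.733 to 0.816) in G2. With library size alone the log2 ratio in G1 was -0.79 in place of -0.17. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the strain effect was -0.29 ± 0.20 log2 (standard error), with an adjusted p of 0.375 and the same direction in 3 of 3 phases. The level of this transcript thus did not separate the strains at the threshold, and where the mutation lies was not analysed here. The gene upstream, ntrY, which encodes the membrane sensor kinase and overlaps ntrX at 1571105 to 1573366, had higher values in ntrX18 in all 3 phases. It stood at 219.9, 314 and 309.9 CPM in Sm1021 and at 766, 734 and 833 CPM in ntrX18, a strain effect of 1.48 ± 0.26 that missed the threshold (adjusted p = 0.0699). Of the paired NtrB-NtrC system, which controls nitrogen assimilation, ntrC stood at 61.8, 71.7 and 67.2 CPM against 16.3, 47.6 and 46.8, a strain effect of -0.997 ± 0.37 (adjusted p = 0.164). The kinase gene ntrB was at -0.49 ± 0.19 (adjusted p = 0.186).

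Genes of the flagellum and of chemotaxis fell in ntrX18. The question was which transcripts differ between strains whatever the phase. The test called 101 genes of 1827 at an unadjusted p under 0.05. Of the 101, 47 were higher and 54 lower in ntrX18, and 35 of the 54 lower genes belonged to the flagella and chemotaxis lists. The split depended on the setting, at 4 higher and 29 lower with library size alone, 138 and 77 with a filter of CPM at least 10 in at least 3 libraries, and 772 and 494 with DESeq2. With strain alone in the fit it was 20 and 60, and 58 of the 101 kept their call. The median strain effect of 32 flagellar genes was -5.49 log2, and 26 of them fell over all genes tested, 31 when adjusted over the list alone. The flagellin gene flaA (chromosome 731285 to 732469), which encodes the filament subunit, fell from 3100, 1318 and 1625 CPM to 121, 69.3 and 124 CPM, a strain effect of -4.21 ± 0.38 (adjusted p = 0.0363). Its adjusted p was 0.0728 without Sm1021 S, 0.125 without Sm1021 G2, 0.0969 without ntrX18 S and 0.155 without ntrX18 G2. Larger falls were those of the rod gene flgC at -7.17 ± 0.45 and the motor switch gene fliM at -5.88 ± 0.26, both with an adjusted p of 0.0157, and of the motor gene motA at -6.24 ± 0.57. Others among the 12 largest falls were flgH, flgF, flgG, flgI, flgK, flgL, fliL and SMc03033, from -6.22 to -5.90. Another rod gene, flgB, had 2 counts in the ntrX18 G1 library, below the 3 read as detected, against 3245 in Sm1021, a ratio of 0.0017 with the prior count (0.00013 to 0.0038 from the counts), and both ends of that interval leave it below the list's median. Its fitted strain effect of -7.58 ± 0.68 rests on these 2 counts too and is no bound. Each of these 12 was lower in 3 of 3 phases, which the rule for naming them required. All 32 listed flagellar genes lay on the chromosome between 711589 and 751436. Of the 42 genes tested there, 31 fell.

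Chemotaxis genes followed, with a median of -2.81 over 19 genes, 9 of which fell over all genes tested and 13 when adjusted over the list alone. The response regulator genes cheY1 and cheY2, whose proteins act on the motor, stood at -4.68 ± 0.26 and -3.57 ± 0.21. The coupling gene cheW1 was at -5.66 ± 0.34, and the receptor gene mcpU fell from 453, 700.0 and 818 CPM to 13.3, 12.4 and 19.9 CPM, all 4 with an adjusted p of 0.0157. By camera the lists' adjusted p were 4.33e-27 for flagella and 1.21e-08 for chemotaxis, but each was 0.568 with an estimated correlation. The number of calls of the strain effect was 3118 without Sm1021 G1 (1586 higher and 1532 lower), 58 without Sm1021 S (11 and 47), 27 without Sm1021 G2 (0 and 27), 3211 without ntrX18 G1 (1856 and 1355), 59 without ntrX18 S (12 and 47) and 0 without ntrX18 G2. Every rise thus lost its call without Sm1021 G2, while 27 of the falls kept it. Of 89 calls of single named genes, here and in the comparisons of phases, all ended without ntrX18 G2, 74 without Sm1021 G2, 50 without either S library and 71 with library size alone.

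The 12 largest rises in ntrX18 included an aldehyde and an alcohol dehydrogenase gene and 6 hypothetical genes. The largest rise was that of gene 1234018, an aldehyde dehydrogenase, from 345, 114 and 22.6 CPM to 8281, 1184 and 625 CPM, a strain effect of 4.25 ± 0.50 (adjusted p = 0.0473). The alcohol dehydrogenase gene adhA1, whose product makes the substrate of such an enzyme, rose by 3.38 ± 0.38 and the oxidoreductase gene 1233276 by 3.47 ± 0.37, both with an adjusted p of 0.0436. An ArsR-family regulator on a megaplasmid, gene 1237852, rose by 2.72 ± 0.22 (adjusted p = 0.0252). The rest of the 12 largest rises lay between 2.499 and 3.07, and were gene 1233571, a glycine-rich wall protein, gene 1237671, a plasmid stability protein, and the hypothetical genes SMa1910, SMa0191, SMa1082, SMa1149, SMc02422 and SM_b21698. All 12 were higher in 3 of 3 phases, again as the rule for naming them required.

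Among the other lists, those of denitrification and of succinoglycan synthesis had higher values in ntrX18. The denitrification list holds genes that respire nitrate and its products, and others grouped with them such as hemN. It had a median of 1.18 over 25 genes, and 18 of these genes rose when adjusted over the list alone. Over all genes tested edgeR called 0 of them, with 19 at an unadjusted p under 0.05, while DESeq2 called 16 and limma-voom 0. The list's adjusted p was 2.13e-06, but 0.568 with an estimated correlation. The nitrous oxide reductase gene nosZ was at 2.77 ± 0.41 and hemN at 2.24 ± 0.33, both higher in 3 of 3 phases (adjusted p = 0.0583 each). Succinoglycan genes, which make the polysaccharide needed for nodule invasion, had a median of 0.85 over 38 genes (adjusted p = 0.000201, and 0.644 with an estimated correlation). For them edgeR called 0 by either adjustment, with 11 at an unadjusted p under 0.05, while DESeq2 called 9 and limma-voom 0. Their first sugar transferase gene, exoY, stood at 119.98, 313 and 271 CPM against 989.8, 1010.4 and 977 CPM, a strain effect of 2.19 ± 0.40 (adjusted p = 0.0706). Genes of galactoglucan, another exopolysaccharide, and quorum sensing were at -0.20 over 20 genes and not called (adjusted p = 0.472). Nitrogen fixation genes were at a median of 0.30 over 43 genes, although library size alone put them at -0.19 in G1 (adjusted p = 0.0336, and 0.644 with an estimated correlation). Among them 1 rose over all genes tested, a copy of the regulator gene fixK (gene 1235444), by 2.44 ± 0.27 (adjusted p = 0.0436), and adjusted over the list alone 15 rose and 2 fell. The call of this list ended without Sm1021 G2 (0.0535), ntrX18 G1 (0.0557) or ntrX18 G2 (0.0531).

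Genes of ATP synthase, the TCA cycle, DNA replication, lipopolysaccharide and the outer membrane were among the other lists with lower values in ntrX18. A length trend was removed only for the flagellar and ribosomal lists and the G1 counts, not for these lists. Spearman's rho between gene length and a gene's level relative to its mean over libraries was 0.179, 0.069 and 0.068 in Sm1021. In ntrX18 it was -0.167, -0.135 and -0.046. ATP synthase genes had a median of -1.20 over 10 genes, the TCA cycle of -0.63 over 17, cobalamin synthesis of -0.65 over 22 and DNA replication of -0.52 over 31, each list with an adjusted p of 0.0020 and of 0.568 with an estimated correlation. Lipopolysaccharide and outer membrane genes, called lipopolysaccharide from here on, were at -0.63 over 34 genes (adjusted p = 0.0010). The members of that list with the smallest p were rkpJ, rkpZ2, rkpU and rkpH, and DESeq2 called 3 of its genes higher and 13 lower. Nodulation genes were at -0.62 (0.00043), phosphate genes at -0.57 (0.0092) and NADH dehydrogenase genes at -0.39 (0.0059). Fatty acid synthesis was at -0.49 (0.0298) and nucleotide synthesis at -0.38 (0.0130). With an estimated correlation the adjusted p of these 6 lists was 0.568 to 0.714. Cytochrome oxidase and bc1 genes, also of aerobic respiration, were at -0.22 over 25 genes and not called (adjusted p = 0.274), with 4 higher and 7 lower at an unadjusted p under 0.05. Members with the smallest p were atpG at -1.49, the complex I gene nuoI at -1.28, the phosphate transporter gene pstC at -1.65 and the plasmid replication gene repC2 at -1.42, with adjusted p of 0.0841, 0.0624, 0.0611 and 0.0583. In the 10 called lists edgeR and limma-voom called 0 genes over all genes tested, with 6 to 17 per list at an unadjusted p under 0.05 by edgeR and 2 to 16 called by DESeq2. Adjusted over the list alone, 7 ATP synthase, 7 lipopolysaccharide, 7 phosphate, 12 NADH dehydrogenase, 3 replication and 2 cobalamin genes fell, 1 NADH dehydrogenase gene rose and the other lists had 0 calls. The call of fatty acid synthesis ended without Sm1021 S (0.126), Sm1021 G2 (0.125), ntrX18 S (0.126) or ntrX18 G2 (0.126), and that of nucleotide synthesis without the same libraries (0.452, 0.225, 0.447 and 0.227). The call of the TCA cycle ended without Sm1021 S (0.0544) or ntrX18 S (0.0551), and that of NADH dehydrogenase without Sm1021 G1 (0.0843) or ntrX18 G1 (0.0719).

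**Figure D1:**
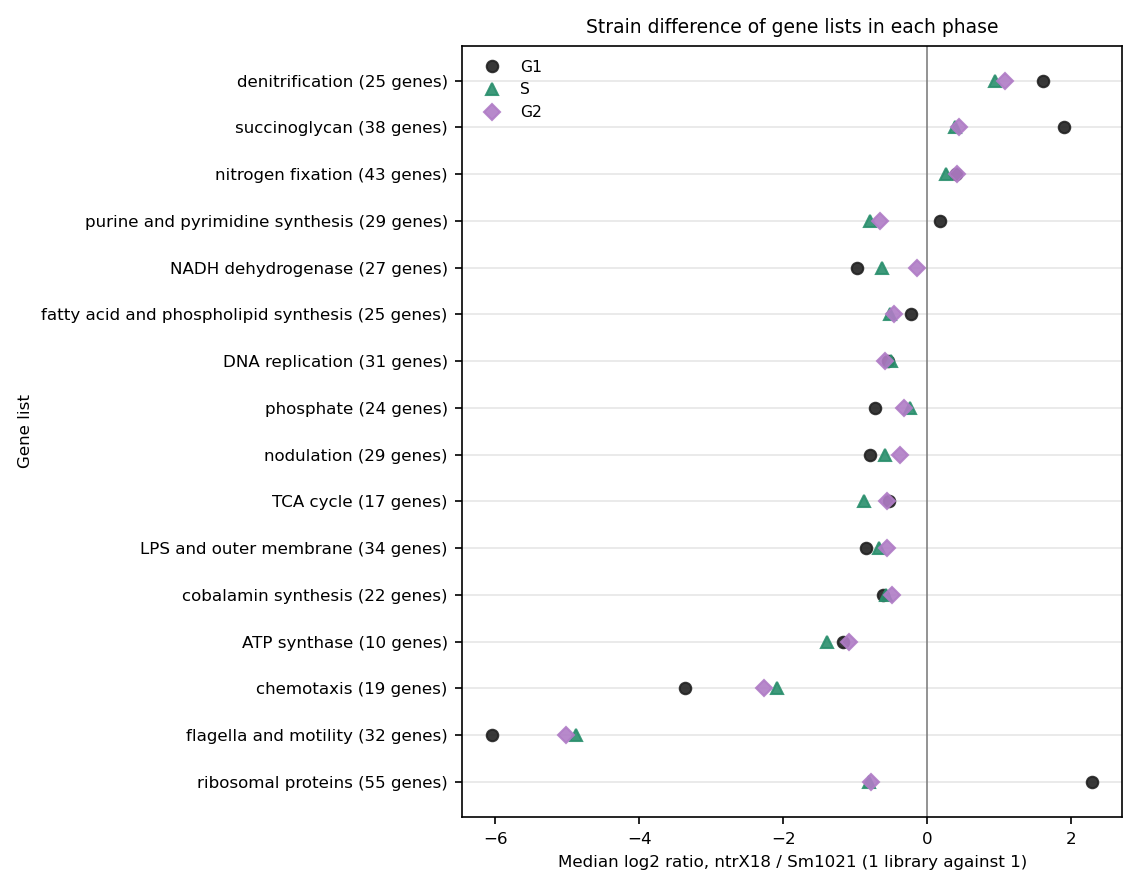
Median log2 ratio of ntrX18 to Sm1021 (x axis) for 16 gene lists, with 1 point for each of G1, S and G2, each from 1 library per strain. Flagellar genes lie at -6.04, -4.89 and -5.02, and ribosomal protein genes at 2.29 in G1 against -0.80 in S and -0.78 in G2.

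The strains differed by more genes in G1 than later. The question was in which phase ntrX18 departs from Sm1021, and these values rest on 1 library each. Past the size rule there were 2347 genes in G1, 1190 in S and 786 in G2, which is 46.9%, 24.7% and 16.4% of the genes with enough counts. Higher in ntrX18 were 1091, 697 and 489 of them and lower were 1256, 493 and 297. With library size alone, 24.5% of those in G1 and 72.6% of those in G2 were higher, in place of 46.5% and 62.2%. In G1 the hypothetical gene SMc04164 stood at 244 CPM in Sm1021 and at 52167 CPM in ntrX18, and its levels in S were 671 and 4483 CPM. SMc00821, SMc00800 and gene 1233710, a signal peptide protein, had log2 ratios in G1 of 7.08, 6.57 and 6.55. The lowest ratios in G1 were those of flgB, flgC, motA and gene 1232317, a regulator within the flagellar region, at 522 CPM against 2.83 CPM. In S the largest ratio was that of aceA, the isocitrate lyase of the glyoxylate bypass, at 38.4 CPM against 778 CPM, followed by a sugar transporter and kinase on pSymB (gene 1237284, gene 1237286 and gene 1237283). In G2 it was gene 1234018, followed by SMc02688, the heat shock gene hspC2 and adhA1. The lowest ratios in S were those of flgB, flgC, SMc03033 and mcpU, and in G2 those of flgB, flgC, flgH and flgG.

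Several lists had other ratios in G1 than in S and G2. Ribosomal protein genes, which set the capacity for translation, had a median log2 ratio of 2.29 in G1, above all 10000 random lists of its size, with 55 of 55 positive. In S the median was -0.80 with 50 negative, and in G2 it was -0.78 with 55 negative, both at percentile 0.0. Places among random lists do not allow for genes that vary together, so they do not show that a shift is unusual for such a list. In the test over phases this list was at 0.09 and was not called (adjusted p = 0.472). With an estimated correlation its adjusted p was 0.906. Without any 1 library it was called at the preset correlation, the only one used there, at -0.80 without Sm1021 G1 (1.14e-10) and -0.72 without ntrX18 G1 (2.3e-11), and at 0.73 to 0.77 without an S or G2 library (0.0015 to 0.0059). Succinoglycan genes were at 1.90 in G1, again above all random lists, and at 0.40 and 0.44 later. Pili genes, which form surface appendages, were at -2.13 in G1 (percentile 0.0), -0.50 in S and -0.29 in G2. Flagellar genes were far apart in each phase, at -6.04, -4.89 and -5.02.

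The largest falls from G1 to the later phases in both strains included the Calvin cycle genes cbbP and cbbF and the sulfate activation genes cysN and cysD, and the largest rises included regulators. The question was which transcripts change with phase in both strains alike. From G1 to S the test called 382 genes, 198 higher and 184 lower in S, of 1989 at an unadjusted p under 0.05. From G1 to G2 it called 617, 292 higher and 325 lower, of 2100. The joint test of any phase change, given further below, called 0 genes. The regulator gene 1233735 rose from 47.1 to 1046 CPM in Sm1021 and from 43.5 to 1196 CPM in ntrX18, by 4.62 ± 0.39 log2. Gene 1232776, a regulator, and its neighbour gene 1232777, a transporter, rose by 5.24 ± 0.63 and 5.22 ± 0.36, and the hypothetical genes SMc04168, SMc04327 and SMa0747 by 4.41, 4.24 and 4.21. All 6 had an adjusted p of 0.0457. The phosphoribulokinase gene cbbP of the Calvin cycle fell from 111 to 0.739 CPM in Sm1021 and from 22.0 to 1.30 CPM in ntrX18, a change of -5.71 ± 0.97 (adjusted p = 0.0494). With it fell cbbF at -5.00 ± 0.69, the sulfate activation gene cysN at -4.45 ± 0.49, gene 1233353, a periplasmic binding protein, SM_b20025 and gene 1235850, an aminotransferase. Each of these 12 moved the same way in both strains, which the rule for naming them required. From G1 to G2 the largest rises held SM_b21676 at 4.40 in place of SMc04327. The largest falls held cysD at -5.25 ± 0.53 and a carbon monoxide dehydrogenase (gene 1234675) at -5.16 ± 0.97, in place of cysN and gene 1235850. In either comparison edgeR called 0 genes with library size alone or with phase alone in the fit, while DESeq2 called 1415 from G1 to S and 1582 from G1 to G2. Without Sm1021 G1 there were 3349 calls from G1 to S and 3554 from G1 to G2, without ntrX18 G1 3791 and 3840, without Sm1021 S 0 and 300, without ntrX18 S 0 and 307, and without Sm1021 G2 or ntrX18 G2 0 in both.

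Sugar uptake genes were lower after G1, although library size alone put them at 0.33 from G1 to G2 in ntrX18, and genes of DNA repair, cobalamin synthesis, galactoglucan and lipopolysaccharide were higher. From G1 to S, the 39 sugar and polyol uptake genes had a median of -1.13, with 5 falls over all genes tested and 13 falls and 1 rise adjusted over the list alone (adjusted p of the list 0.0005, and 0.946 with an estimated correlation). Their median from G1 to G2 was -1.02, with 4 falls over all genes tested and 13 falls and 1 rise adjusted over the list alone (0.0034, and 0.934 with an estimated correlation). Members were agpA, of a galactoside transporter, at -2.59 and the xylose genes xylA and xylB at -2.54 and -2.18 from G1 to S. The 24 repair and recombination genes were at 0.58 in S (adjusted p = 0.0006, and 0.946 with an estimated correlation) and 0.67 in G2 (0.0025 and 0.903), with 1 rise, that of the Holliday junction resolvase gene ruvC by 2.05 ± 0.27 in S. Adjusted over the list alone, 5 rose in S and 1 in G2. Cobalamin genes were at 0.62 with 2 rises in S and 0.75 with 5 in G2, and 9 rises and 1 fall in each adjusted over the list alone. Galactoglucan genes, of the other major exopolysaccharide, were at 0.68 in S and 0.95 in G2, and lipopolysaccharide genes at 0.58 and 0.69. In these lists edgeR called 0 by either adjustment, with 4 and 8 galactoglucan and 10 and 12 lipopolysaccharide genes at an unadjusted p under 0.05, while DESeq2 called 2 and 2, and 9 and 11, and limma-voom 0 and 0, and 1 and 1. Succinoglycan genes were at 0.47 in S, with 3 rises by either adjustment (exoZ, exoQ and exoI). In G2 they were at 0.39 and not called (adjusted p = 0.0639), with a median ratio of G2 to G1 of 1.30 in Sm1021 and of 0.02 in ntrX18, where 19 were positive and 19 negative. Nitrogen fixation genes from G1 to G2 were at -0.92 with 5 falls, 6 adjusted over the list alone, among them the regulator gene nifA at -1.66, and denitrification genes at -0.74 with 1 fall by either adjustment, that of napD at -3.05. The adjusted p of the lists was 0.0156 to 0.0426 in S and 0.0034 to 0.0294 in G2 for those not given above. With an estimated correlation it was 0.946 for each list in S and 0.903 to 0.934 in G2, so no call of a list held. From G1 to S, calls ended without Sm1021 G1 for succinoglycan (0.633), lipopolysaccharide (0.0767) and cobalamin (0.0767), without Sm1021 S for succinoglycan (0.178), and without ntrX18 G1 for galactoglucan (0.135). From G1 to G2 they ended without Sm1021 G1 for nitrogen fixation (0.103), sugar uptake (0.103), lipopolysaccharide (0.0690) and cobalamin (0.0682), without ntrX18 G1 for nitrogen fixation (0.0953) and denitrification (0.175), and without ntrX18 G2 for galactoglucan (0.0773) and lipopolysaccharide (0.0565).

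**Figure D2:**
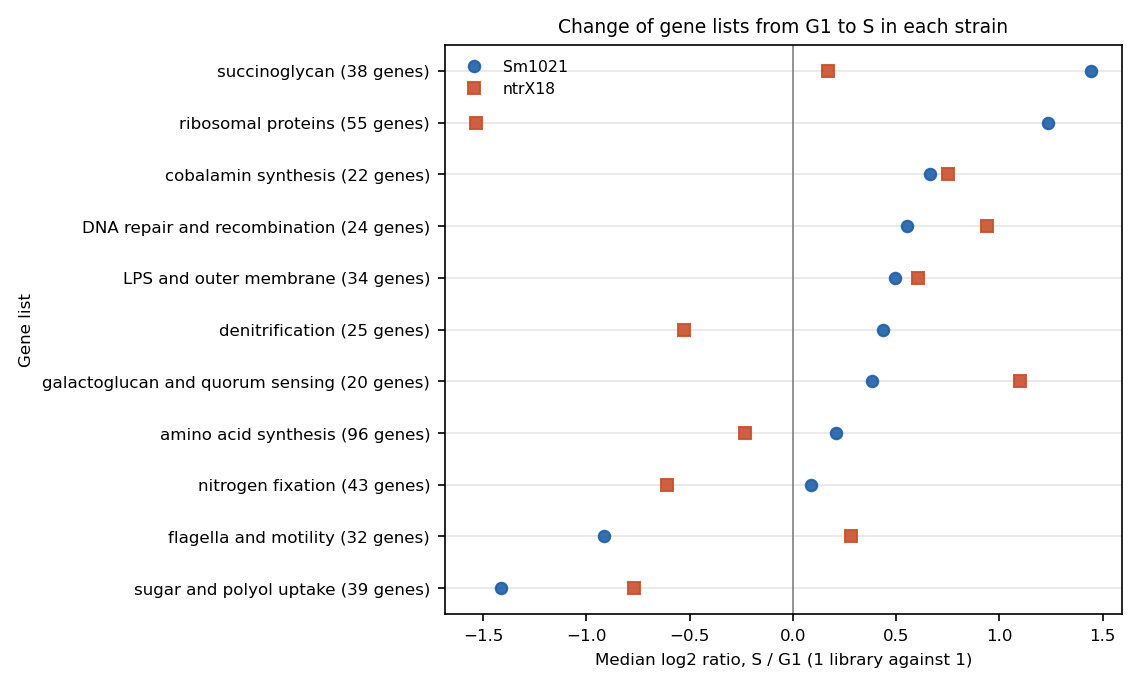
Median log2 ratio of S to G1 (x axis) for 11 gene lists, with 1 point for Sm1021 and 1 for ntrX18, each from 1 library per phase. Ribosomal protein genes lie at 1.24 in Sm1021 and at -1.54 in ntrX18, and sugar uptake genes at -1.41 and -0.77.

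Between S and G2, transcripts of both strains were nearly alike. The test called 0 genes by edgeR, DESeq2 and limma-voom, with 42 at an unadjusted p under 0.05 by edgeR. Those 42 are fewer than a share of 0.05 of the 6128 genes tested, which would be reached with no change at all. The error of this test also holds the strain difference in G1, so the 0 calls are no evidence that nothing changed. The likeness rests on the r between S and G2, 0.992 in Sm1021 and 0.987 in ntrX18. The 5 genes with the smallest p were SMa0633, SMc01961, SMc00115, SMa5018 and SMa1169, at -1.30, 1.77, 1.72, 2.13 and -1.07, each with an adjusted p of 1. The joint test of any phase change called 0 genes, with 1728 at an unadjusted p under 0.05, while DESeq2 called 1356 and limma-voom 0. Leaving out 1 library changed that count of 0 to 3125 without Sm1021 G1, 3575 without ntrX18 G1, 25 without Sm1021 S and 136 without ntrX18 S. Small median shifts from S to G2 were called by camera in 6 lists. By edgeR, DESeq2 and limma-voom 0 of their members were called, with 3 nitrogen fixation and 2 denitrification genes at an unadjusted p under 0.05 by edgeR and 0 in the others. The lists were osmoprotectant uptake at 0.30, chemotaxis at 0.21, flagella at 0.14, phosphate at -0.16, nitrogen fixation at -0.18 and denitrification at -0.53, with adjusted p of 0.722 for osmoprotectants, nitrogen fixation and denitrification and 0.959 for the others with an estimated correlation. The call of chemotaxis ended without Sm1021 S (0.679) or ntrX18 G2 (0.479), that of phosphate without Sm1021 G2 (0.932) or ntrX18 S (0.586), and that of osmoprotectants without ntrX18 S (0.108) or ntrX18 G2 (0.321). That of flagella ended without ntrX18 G2 (0.962) and with library size alone (0.0632), and without Sm1021 S the list was called in the opposite direction (-0.23, adjusted p = 0.0446). The sign also turned for phosphate without ntrX18 S (0.023), and for chemotaxis (-0.18) and osmoprotectants (-0.099) without ntrX18 G2.

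Within each strain most of the change lay between G1 and S. The question was which genes cycle differently in ntrX18, and the difference between strains was not tested, because no library is repeated. In Sm1021, 2163 genes passed the size rule from G1 to S, 2164 from G1 to G2 and 45 from S to G2. In ntrX18 these numbers were 1854, 2093 and 116. The changes of the 2 strains were compared over 4980 genes with a mean CPM of at least 10 across all 6 libraries. That set of genes is not the one behind the counts above. The log2 changes from G1 to S had a Pearson r across genes of 0.549 between the strains, and from G1 to G2 of 0.531. From G1 to S, 443 genes were higher in both strains and 506 lower in both, against 183.6 and 220.6 for independent lists. Opposite directions were rarer than for independent lists, at 91 genes higher in Sm1021 and lower in ntrX18, against 209.5, and 45 the other way, against 193.3. With library size alone, 80.7% of the ntrX18 genes past the size rule from G1 to S and 79.7% of those from G1 to G2 were higher in the later phase, in place of 44.3% and 46.1%.

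The branched-chain amino acid permease genes livF, livG and livM, taken up among the largest differences, and ribosomal protein genes had opposite ratios of S to G1 in the strains. The leucine binding protein gene livK (chromosome 2668389 to 2669507) stood at 12640 CPM in Sm1021 G1 and at 285 CPM in S, against 305 and 134 CPM in ntrX18, lower in S in both. The permease genes livF, livG and livM beside it had log2 ratios of S to G1 of -2.43, -2.32 and -2.31 in Sm1021 and of 2.38, 2.46 and 1.98 in ntrX18. Gene 1237203, a transporter ATPase, was at 0.36 and 5.03. Toward lower values in ntrX18 were SMc04164 at 1.46 and -3.54, sucB 1236435, annotated as a TCA cycle enzyme on pSymB, at 2.04 and -3.03, SMc00703 at 2.78 and -2.09 and the chorismate mutase gene pheAa at 3.50 and -1.31. From G1 to G2 the largest differences included livK, exsB and SMc00821 as well, at 4.55, -5.46 and -5.45. From S to G2 they were higher in ntrX18 for gene 1235426, gene 1237690, the asparagine synthetase gene asnB and xdhB1, by 1.67 to 2.99. They were lower for aceA, nex18, SM_b20025 and SM_b21481, from -3.23 to -2.10. Ribosomal protein genes had a median log2 ratio of S to G1 of 1.24 in Sm1021, with 55 of 55 positive, and of -1.54 in ntrX18, with 55 of 55 negative. Their median level was 535, 1245 and 1147 CPM in Sm1021 and 2575, 805 and 713 CPM in ntrX18. Flagellar genes were at -0.91 in Sm1021 and 0.28 in ntrX18, and succinoglycan genes at 1.45 and 0.17.

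Genes of cell division had their largest differences between strains in the G1 libraries for ftsZ1, ftsZ2 and minC. The tubulin-like division genes ftsZ1 and ftsZ2 had opposite differences in G1, with ftsZ1 at 2805, 1108 and 1210.3 CPM in Sm1021 and 626, 1139.6 and 1269 CPM in ntrX18. ftsZ2 stood at 424, 816 and 694 CPM against 3722, 1147 and 948 CPM. The strain effects were -0.65 ± 0.61 (adjusted p = 0.508) and 1.30 ± 0.71 (adjusted p = 0.280). The genes minC, minD and minE, which place the division site, were higher in ntrX18 in 3 of 3 phases, by 1.23 ± 0.49, 0.88 ± 0.31 and 0.84 ± 0.30 (adjusted p = 0.186, 0.157 and 0.153). The master regulator gene ctrA stood at 1712, 1300.0 and 1343 CPM against 1462, 1253 and 1494 CPM, a strain effect of -0.04 ± 0.30 (adjusted p = 0.938). The replication initiator gene dnaA was at -0.35 ± 0.25 (adjusted p = 0.388). The DNA methylase gene ccrM was at 419.8, 289.8 and 295 CPM against 154, 279 and 369 CPM, and at -0.38 ± 0.43 (adjusted p = 0.585). The pilin gene pilA1 stood at 761, 64.6 and 71.6 CPM against 95.9, 16.3 and 44.1 CPM, with a strain effect of -1.90 ± 0.52 (adjusted p = 0.111) and a change from G1 to S of -3.16 ± 0.65 (adjusted p = 0.0604). As lists, the cell cycle regulators had a median strain effect of -0.36 over 4 genes (adjusted p = 0.274) and cell division genes of -0.36 over 22 (adjusted p = 0.469). In the comparisons of phases neither was called.

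**Figure D3:**
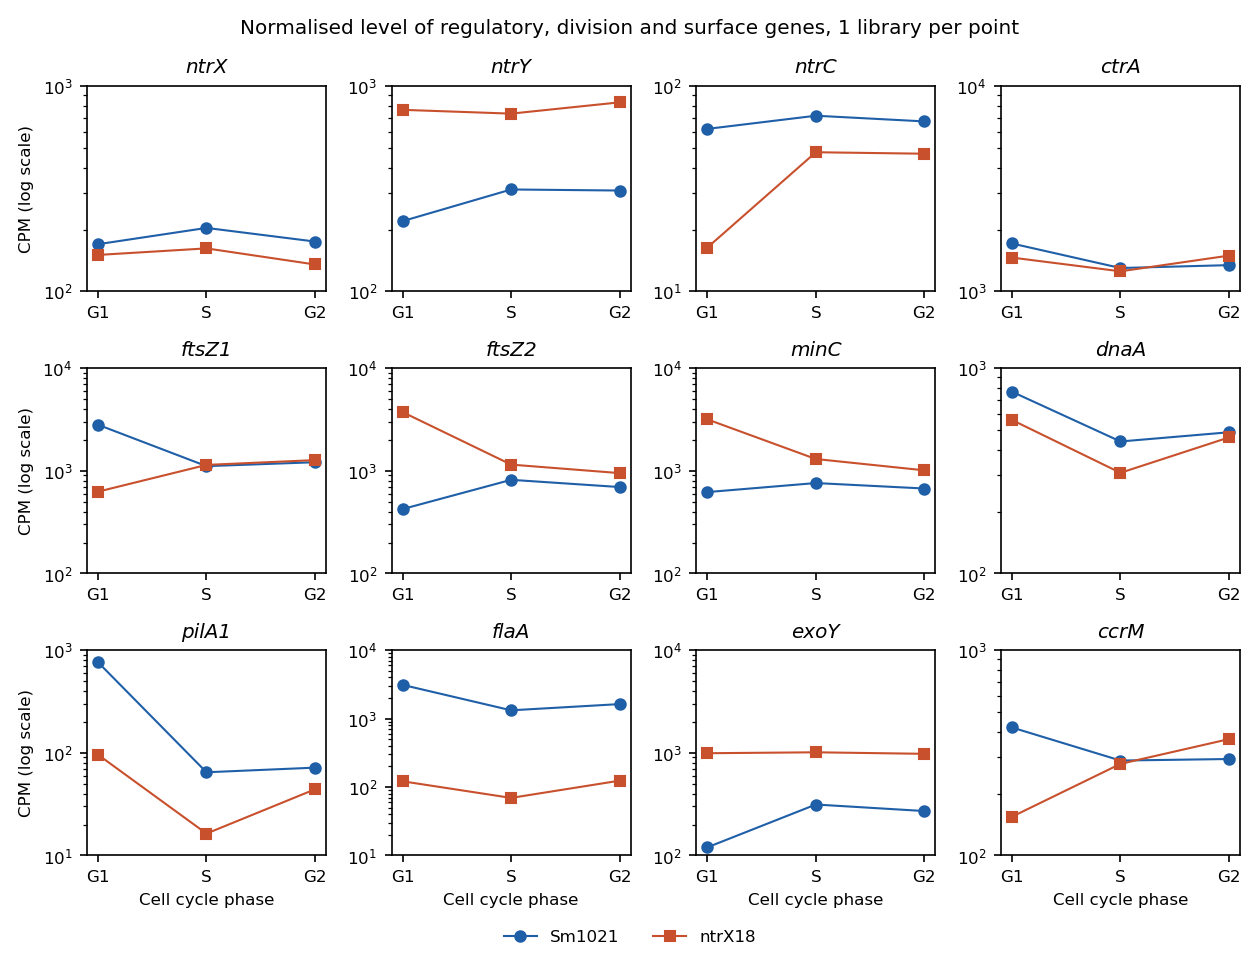
CPM on a log axis against phase for 12 genes, with 1 line per strain and 1 library per point. The lines of flaA and ntrY stay apart in all 3 phases, and those of ftsZ1 and ftsZ2 are far apart in G1 and close in S and G2.

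The chromosome held a slightly smaller mean share of the counts in ntrX18 and both megaplasmids a slightly larger one, with no difference past a test. The chromosome held 85.6% ± 1.77 (SD, n = 3) of the counts in Sm1021 and 83.0% ± 1.55 in ntrX18, with a two-sided exact permutation p of 0.2. The symbiotic megaplasmid pSymA held 4.29% ± 0.393 and 5.46% ± 1.16 (n = 3, exact permutation p = 0.3), and pSymB held 10.1% ± 1.38 and 11.6% ± 0.388 (n = 3, exact permutation p = 0.2). With 3 libraries against 3 the smallest p such a test allows is 0.1, so a difference could not pass the threshold. The test sets phase aside, and the order of the strains in G1 was the reverse of that in S and G2. In the order G1, S, G2, the chromosome held 83.6%, 86.8% and 86.4% in Sm1021 and 84.7%, 82.2% and 81.9% in ntrX18. The shares of pSymA were 4.73%, 3.97% and 4.17% against 4.13%, 5.98% and 6.27%, and those of pSymB 11.7%, 9.21% and 9.47% against 11.1%, 11.8% and 11.8%. Without the 20 most abundant genes the strains were closer in G1, with 80.0% and 80.4% for the chromosome and 5.75% and 5.32% for pSymA, and pSymB was no longer reversed, at 14.2% and 14.3%.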

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

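The tests of a mislabelled G1 library, of incomplete synchrony and of low counts of the typical gene in ntrX18 G1 were chosen only after the results were seen, and so were the conditions that picked the results of this part, namely opposite signs in both comparisons, with a log2 ratio of at least 1 for a gene. Ratios and list medians come from 1 library against 1 and were not tested, apart from the fitted strain effect of the flagellar list. Genes taken up because their phase changes differ between the strains tend to show opposite signs by that choice alone.

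Ribosomal protein genes had opposite ratios in the strains, with a median log2 ratio of S to G1 of 1.24 in Sm1021 and -1.54 in ntrX18, and of G2 to G1 of 0.97 and -1.72. Read across strains, ntrX18 against Sm1021 stood at 2.29 in G1, -0.80 in S and -0.78 in G2. The tables argue against gene length, since the difference between strains in the ratio of S to G1 was 2.52 log2 after a length trend was removed from each library, and against the scaling, since the smallest difference over RLE factors and library size was 2.08. If ntrX18 cells changed as Sm1021 cells do, a mixture of G1 and S cells in the ntrX18 G1 culture would put its median between 0 and the Sm1021 value. The median of -1.54 lies outside. The ratio in fully synchronised ntrX18 cells was not measured, however, so this value cannot decide on incomplete synchrony. Among what stays open is incomplete synchrony, or a difference between the strains in the response to starvation or in the timing of sampling. Any of these may hold for this 1 pair of G1 libraries only. The response to starvation and the timing of sampling were not tested, nor were technical differences of these libraries other than gene length and scaling.

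The strain difference was larger in G1 than later, with 2.38 times as many genes past the size rule as the mean of S and G2. That ratio was 2.35 without the 20 most abundant genes and 2.30 with the length trend removed, which argues against each of these as the whole cause. It was 2.37 with every library thinned to 1 total count, but the totals differed by 1.22-fold at most, so this did not test depth. The count of the median tested gene differed more, at 322 in ntrX18 G1 against 572.5 to 659 in the others. Thinned so that it was 321 to 373 in every library, the ratio was 2.34, which argues against low counts of the typical gene. A G1 library carrying the wrong strain label is excluded by the flagellar genes, whose median strain difference in G1 was -6.04. Among what stays open is a strain difference in the starved cells that precede release into the cycle, or a culture of either strain taken at another point of G1. With 1 G1 library per strain these biological explanations could not be tested. Technical differences of the G1 libraries other than those examined above were not tested either and stay open too.

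Flagellar genes were lower in ntrX18 in all 3 phases, with a median between -6.04 and -4.89. No single library made this, since the median of the strain effect closest to 0 with 1 library left out was -4.84. With all libraries that list was called (adjusted p = 4.33e-27), but not with an estimated correlation (0.568). Gene length did not either, since the median closest to 0 over the 3 phases was -4.87 with the length trend removed. A candidate explanation is loss of a regulator of the whole flagellar region in ntrX18, but whether ntrX acts on it, or the strain carries another difference, was not tested.

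The branched-chain amino acid permease genes had ratios of S to G1 of -2.43 in Sm1021 and 2.38 in ntrX18 for livF, -2.32 and 2.46 for livG, and -2.31 and 1.98 for livM. The reverse, higher in S in Sm1021 and lower in ntrX18, was seen for SMc04164 at 1.46 and -3.54, SMc00800 at 1.91 and -1.73, and gene 1233710 at 1.29 and -2.53. It was also seen for sucB 1236435 at 2.04 and -3.03, SMc00703 at 2.78 and -2.09, pheAa at 3.50 and -1.31, and exsB at 2.44 and -2.25. Between strains, gene 1237203 was at -1.83 in G1 and 2.84 in S, and pheAa at 3.38 in G1 and -1.42 in S.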

How the results depend on the processing

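The fit without both G1 libraries was chosen only after the results were seen; the other alternatives were fixed before. Each group holds 1 library and the labels give no replicate numbers, so the strains could be paired only by phase. The main fit did so with phase as a term, and strain alone gave 80 calls, 58 of them among the 101. Leaving out rRNA and tRNA genes was not run, since the table holds none, and a pseudocount on FPKM was not needed, since counts were tested. With 1 library per cell, leaving one out assumes that the lone library of that cell varies like the others. The strain effect with phase in the fit gave 101 calls, and 105 to 126 with no filter, RLE factors or limma-voom. Directions of the 89 calls of named genes held under every alternative that tested them, and all 89 kept their call with DESeq2, RLE factors and limma-voom, 18 with library size alone. Many of these genes were named only if they had 1 direction in every phase or strain. For those, a direction that holds without 1 library was in large part fixed by that choice and is no support. Of the 34 calls of lists, 31 were kept with library size alone and 32 over members with a mean CPM of at least 10.

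The strain effect gave 215 calls (138 up and 77 down) with a filter of CPM at least 10 in at least 3 libraries, 1266 (772 and 494) with DESeq2, 33 (4 and 29) with library size alone and 3111 without both G1 libraries, which held all 101. DESeq2 gave 1415 calls from G1 to S, 1582 from G1 to G2 and 1356 for any phase. Library size alone, and phase alone, gave 0 from G1 to S and 0 from G1 to G2. Without 1 library the ranges were 0 to 3211 for strain, 0 to 3791 from G1 to S, 0 to 3840 from G1 to G2 and 0 to 3575 for any phase. The error then rests on fewer libraries, since the other library of the same phase is fitted exactly and adds nothing to it. Without either G1 library it rests on the S and G2 pairs alone, and S and G2 were nearly alike within each strain. With a minimum mean CPM of 50, genes past the size rule between strains were 1397 in G1, 719 in S and 488 in G2. Within Sm1021 they were 1270 from G1 to S, 13 from S to G2 (83 at a minimum of 1) and 1260 from G1 to G2, and within ntrX18 1127, 50 and 1238. These minimums test other numbers of genes.

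Gene lists called were 0 in each of the 4 comparisons with an estimated correlation and 0 with fry. Without 1 library, lists called ranged from 14 to 18 for strain, 6 to 14 from G1 to S, 8 to 15 from S to G2 and 6 to 15 from G1 to G2. Ribosomal protein genes reversed, to -0.80 in the strain effect without both G1 libraries. Without 1 library they ranged from -0.80 to 0.77 for strain (-0.72 without ntrX18 G1), -1.54 to 1.23 from G1 to S (0.38 without ntrX18 S), -1.13 to 0.75 from S to G2 (0.40 without ntrX18 G2) and -1.72 to 1.02 from G1 to G2. From S to G2 the ranges were -0.23 to 0.53 for flagella, -0.18 to 0.36 for chemotaxis, -0.28 to 0.023 for phosphate, -0.40 to 0.21 for sigma factors (0.094 without ntrX18 G2) and -0.099 to 0.33 for osmoprotectants. For genes they were -0.63 to 0.95 for ccrM from G1 to S, -1.35 to 0.87 and -1.19 to 1.01 for ftsZ1 from G1 to S and to G2, and -1.71 to 0.95 and -1.96 to 0.72 for ftsZ2. With library size alone, nitrogen fixation reversed to -0.19 in the G1 strain ratio and to 0.061 in the ratio of S to G1 in ntrX18. Denitrification reversed to 0.15 in that ratio and to 0.085 in the strain difference of G2 to G1. Sugar uptake reversed to 0.33 in the ratio of G2 to G1 in ntrX18, and amino acid synthesis to 0.26 and 0.28 in the strain difference of S to G1 and of G2 to G1. Each of these ratios with library size alone uses the ntrX18 G1 library, whose median gene that scaling moved by -0.55 log2. The ribosomal reversals go with the strains' opposite ratios of S to G1, 1.24 in Sm1021 and -1.54 in ntrX18. A fit without ntrX18 G1 rests on Sm1021 G1 alone for that phase, and gave 1.23 from G1 to S. Other causes were not tested, nor were those of the other reversals.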

Other observations

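The lists of this part, and the genes trkA and 1233116, were chosen only after their values were seen, while the test of gene position and the count of other splits were fixed before. The other genes are those that the rule for naming genes gives for these lists.

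The betaine genes betI, betC and betA rose from G1 to G2, and betI alone from G1 to S. The repressor gene betI, which controls the uptake and use of choline as an osmoprotectant, rose by 3.37 ± 0.53 log2 from G1 to S (adjusted p = 0.0486 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) and by 3.44 to G2 (0.0400). The genes betC and betA, for enzymes that make choline and oxidise it, rose by 2.36 each from G1 to G2 (0.0393 and 0.0458), but missed the threshold from G1 to S (0.0514 and 0.0781), as did betB from G1 to G2 (0.0617). The 3 called genes had the same direction in 2 of 2 strains. As a list, osmoprotectant uptake was not called from G1 to S (median 0.68, adjusted p = 0.157) or from G1 to G2 (0.73, adjusted p = 0.0639), and adjusted over the list alone 6 genes rose and 1 fell from G1 to G2. From G1 to G2 the adjusted p of these 3 genes was 0.276 to 0.294 without Sm1021 G2, 0.252 without ntrX18 G2 and 0.0600 to 0.0661 with library size alone. That of betI from G1 to S was 0.118 without Sm1021 G2, 0.115 without ntrX18 G2, 0.245 without Sm1021 S, 0.150 without ntrX18 S and 0.0829 with library size alone.

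The median level of 11 alternative sigma factor genes, which direct RNA polymerase to particular sets of genes, was highest in the ntrX18 G1 library. It was 86.3, 130.3 and 151 CPM in Sm1021 and 979, 210.03 and 123 CPM in ntrX18. As a list they had a median strain effect of 0.29, with 8 of 11 positive, and were not called (adjusted p = 0.0912, and 0.680 with an estimated correlation), although the list was called without any 1 of the S and G2 libraries (0.0138 to 0.0301). The heat shock sigma factor genes rpoH1 and rpoH2 had strain effects of 2.22 ± 0.48 and 2.502 ± 0.91, and rpoE5 of 3.58 ± 0.97, none past the threshold (adjusted p = 0.0855, 0.163 and 0.109). Across phases rpoE4 fell by 2.56 log2 from G1 to S in both strains (adjusted p = 0.0486). From G1 to G2 edgeR called 2 of these 11 genes. The hydrogen peroxide regulator gene oxyR rose in ntrX18, from 45.8, 65.8 and 59.98 CPM to 273, 274 and 239.6 CPM, a strain effect of 2.21 ± 0.24 (adjusted p = 0.0436). Without Sm1021 S, Sm1021 G2, ntrX18 S or ntrX18 G2 the adjusted p of oxyR was 0.112, 0.173, 0.115 and 0.173, and that of rpoE4 was 0.394, 0.126, 0.264 and 0.125. With library size alone they were 0.0650 and 0.0765.

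Near ntrX on the chromosome, the D-amino acid aminotransferase gene 1233116 (1576163 to 1577026) fell in ntrX18, from 112, 83.7 and 77.5 CPM to 20.7, 17.1 and 18.7 CPM. The strain effect was -2.26 ± 0.21 (adjusted p = 0.0364), and its adjusted p was 0.108 without Sm1021 S, 0.162 without Sm1021 G2, 0.102 without ntrX18 S, 0.160 without ntrX18 G2 and 0.0792 with library size alone. The potassium uptake gene trkA, between it and ntrX, was at 1.40 ± 0.22 (adjusted p = 0.0620).

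The hypothesis that chromosomal genes near the start of the sequence numbering gain transcript in S, as their copy number would during replication, was tested over 3351 genes. Spearman's rho across genes between the log2 ratio of S to G1 and the distance from position 1 was 0.0043 in the strain with the higher value and -0.027 in the other, inside the middle 95% of circular shifts in both strains. The position of the replication origin was not given in the sources used here, and the lowest rho over all rotations was -0.087 in one strain and -0.070 in the other. Copy number along the chromosome, measured from position 1, thus did not explain the ratio of S to G1.

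Of the 10 splits of the 6 libraries into 3 and 3, only 1, the real one, called 101 genes or more for the strain effect, and the highest count of the others was 0. With 10 splits a share under 0.05 cannot be reached. In the other splits the strain difference itself enters the error of the fit, so their counts are no measure of chance.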
